A study of Mus musculus with 2 samples.

How the data were processed

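Oct4 (the product of Pou5f1, a transcription factor of pluripotent cells) was profiled by sequential chromatin immunoprecipitation in ZHBTc4 F-Oct4 cells, a mouse embryonic stem cell line that carries Flag-tagged Oct4. Per the labels' protocols, cross-linked chromatin was sonicated to between 100 and 500 bp, bound with anti-Flag antibody and released with Flag peptide. The eluate was then bound a second time, either to beads carrying sWGA, a lectin that binds N-acetylglucosamine, or to control beads, and was released with 0.5 M GlcNAc. The labels name the control in 3 ways, as an input, as an IgG second step and as plain agarose beads, and which of these it was is not resolved here. Fragments of 200 to 300 bp were amplified over 18 PCR cycles and read for 76 cycles from a single end on an Illumina Genome Analyzer II. There was 1 library per group, so no comparison between the groups has a replicate error.

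The aligner and the read filter are not given in the sources used here. The genome build was mm9, per the submitters' processing notes. Per the file headers, regions were called with MACS 1.4.1 at a p cutoff of 1e-05, which is a score of 50, with an effective genome of 1870 Mb, a fragment length of 155 bp and local background windows of 1 kb and 10 kb. Duplicate tags were limited to 2 per position in the sWGA library and to 1 in the control, and the smaller library was scaled up to the larger, per the file headers. The list deposited for the control has no header and is named as the negative list of the same run, in which MACS exchanges treatment and control. The regions of both lists were thus called on 1 library against the other, with no pooling.

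The deposited tag counts are whole, unscaled tags per region in the library that served as treatment. The deposited score is 10 times the negative log10 of the caller's p-value. The deposited fold is a ratio of the tag height at the summit to the larger of the genome-wide and local expectation. In the control list that height is in unscaled control tags, as read from its values: 36.1% of its folds were whole tags, within 0.01, over the genome-wide expectation of the sWGA library. Folds of the lists are therefore not on the same scale. The deposited FDR is a percent that the authors' caller derived from the exchanged run, and it is given for the sWGA list only. Scores, folds and FDR values are the authors' unless a value is said to be scored again or recomputed, and regions are ranked only within their own list. Positions are 1-based mm9 coordinates as deposited.

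The header gives 16695056 sWGA tags, of which 6129874 (36.7%) remained after filtering, and 366466 control tags, of which 78351 (21.4%) remained. After filtering the sWGA library was 78.2 times deeper, so that 1 control tag stood for 78.2 sWGA tags in the caller. A median sWGA region would hold 1.37 sWGA tags and 0.0176 control tags if tags were spread evenly. Intervals on counts of tags or regions cover counting error only. They treat regions as independent, which neighbouring peaks are not.

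Values were computed from the lists with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. Regions were scored again as the Poisson chance of more than the region's tags at a stated rate per bp. At the genome-wide rate this gave the deposited score within 0.02 for 97.6% of the 26366 peaks of at least 311 bp that had that background. Lists were compared by counts, by medians and quartiles, and by overlap of at least 1 bp. Chromosome densities were divided by the position of the last region listed on the chromosome in either list, and set against all other autosomes with an exact (Clopper-Pearson) 95% interval on the ratio. Neighbouring summits within 5 kb and, as had been planned, overlaps were set against 1000 random placements on the same chromosomes, uniform over the listed span. The percentile of the observed value among these placements describes these libraries and is not a test of the conditions. A percentile under 2.5 or over 97.5 was called. For overlaps it carries no information, since each list was called against the other library, and it is not reported. The placement steps were tested on simulated data: with 33783 unrelated summits 1 of 20 runs was called, and with 10% of summits moved beside another all 20 were. With 750 unrelated control regions 0 of 20 runs were called, and with 10% laid on peaks all 20 were. Unrelated summits and regions were drawn by the same uniform placement, so these runs check the computation and not whether that placement suits real peaks.

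The alternatives were a minimum score of 100, a minimum fold of 10, a maximum FDR of 1%, other distances and other overlap rules, all set before the data were examined. A maximum FDR of 5%, placement within 250 kb, a minimum of 18 tags, joining of peaks within 10 kb and exclusions of single chromosomes or dense groups were added after. The rule for named regions, also set before, took the 10 sWGA peaks with the highest fold, the 10 with the highest score and the 5 control regions with the highest score. No mm9 sequence or gene annotation was used here, so the comparisons with promoters, motifs and gene groups that had been planned were not analysed here, and regions are named by position alone.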

Results

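The study sought where Oct4 taken to carry O-linked N-acetylglucosamine, through the lectin sWGA, sits on chromatin of mouse embryonic stem cells. The chromatin was cross-linked, so the sWGA step by itself does not show that Oct4, and not another protein nearby, bound the lectin. The sWGA second step gave 1 library of 6129874 tags after filtering, and the control second step gave 1 library of 78351. The list called on the sWGA library held 33783 peaks. The list called on the control library, with the sWGA library as its background, held 750 regions. Values below are therefore single measurements without replicates, and no p-value between the conditions is given.

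The sWGA peaks outnumbered the control regions 45.0 to 1 and covered 14.7 Mb against 0.211 Mb. They held 515698 tags, or 8.41% of the filtered sWGA tags, whereas the control regions held 3703 tags, or 4.73% of the filtered control tags. At a deposited score of at least 100 the sWGA list held 11464 peaks. All 750 control regions passed that score with their tags scaled up by the caller, whereas their median score was 97.8 when scored again at the control library's own depth. The sWGA library was 78.2 times deeper than the control, so these counts compare the lists as called and not the 2 precipitations at equal depth.

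Most sWGA peaks were weak. The median peak was 419 bp long and held 11 tags, with quartiles of 10 and 16 tags, and 21052 peaks (62.3%) held 9 to 12 tags. The median fold over the caller's background was 15.75, with quartiles of 11.81 and 19.68, and the median score was 79.96. A strong tail was present: 7214 peaks (21.4%) held at least 18 tags, 53 held at least 100 tags and 52 scored over 1000. Control regions rested on far fewer tags, since 575 of 750 (76.7%) held 3 tags. Of the 750 control regions, 685 (91.3%) reached a score of 3100 or more.

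The peak with the highest fold lay on chromosome 8 at 20019707 to 20020631, with 212 tags, a fold of 328.68 and a score of 3037.01. A second peak on chromosome 8, at 19784317 to 19785305, held 289 tags, the most of any peak, at a fold of 75.87. The first fold was whole tags over the genome-wide expectation. The second was whole tags over the higher expectation that 1 control tag within 10 kb sets, so the folds have different backgrounds. These peaks started 235 kb apart. The highest score, 3100, which is read here as a ceiling, belonged to a peak on chromosome 11 at 102190599 to 102191514. It held 223 tags at a fold of 283.41. Another of the 10 peaks with the highest fold, at 102017552 to 102018094 on the same chromosome, held 88 tags at a fold of 157.45. A compact peak of 381 bp on chromosome 4, at 153349020 to 153349400, held 111 tags at a fold of 194.85. Chromosome 15 had a peak at 76437749 to 76438589 with 128 tags and a fold of 188.94, and chromosome 13 had one at 66811776 to 66812510 with 146 tags and a fold of 153.52. A peak on chromosome 17 at 37215621 to 37216467 held 122 tags at a fold of 177.13, and one on chromosome 19 at 3282704 to 3283224 held 116 tags at a fold of 175.17. The 14 peaks named by the highest fold or score, 6 of them by both, lay on 11 chromosomes and held 88 to 289 tags. The other 5 were on chromosomes 1 (from 133763471), 7 (from 27491254), 8 (from 112089120), 10 (from 79711469) and 12 (from 14095552).

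In the control list the highest score, 3223.52, went to a region of 3 tags on chromosome 18 at 28285670 to 28285985. The next were a region of 11 tags on chromosome 9 at 3001289 to 3001565 and a region of 3 tags on chromosome 11 at 44470402 to 44470732. A further 8 regions of 3 tags each tied at 3169.72. Only 13 control regions scored over 3100, and 672 stood at exactly 3100, which is read here as a ceiling of the score. The order by score at or above that value is therefore no order of strength. Ranked by tags, an order chosen after the values were seen, a locus at 98.5 Mb on chromosome 2 stood first. Its 4 control regions held 612 tags, 16.5% of all tags in control regions and 0.781% of the filtered control library, and its strongest region, at 98506318 to 98507574, held 415. The sWGA list had 0 peaks there. The deposited folds of the 2 control regions with the most tags at this locus were 0.47 and 0.14, and both regions scored 3100. Control folds set unscaled control tags against an expectation at the depth of the sWGA library, so that a fold under 1, as in 97 control regions (12.9%), means that sWGA tags were also present and not that the control was below its scaled background. The region on chromosome 17 at 39983069 to 39985210 held 100 control tags.

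The lists did not share regions. Of 750 control regions 0 overlapped an sWGA peak, and 2 had one within 1 kb, at 179911755 to 179912122 on chromosome 1 and at 3202366 to 3202756 on chromosome 7. The calling itself kept the lists apart: each was called with the other library as background, and 3 control tags weighed as much as 235 sWGA tags, a number that 2 sWGA peaks exceeded. The absence of overlap is therefore no measure of how the precipitations differ.

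The sWGA peaks were spread over the autosomes and were sparse on chromosome X. The 19 autosomes held 33200 peaks at 13.4 per Mb. Chromosome X held 577 peaks at 3.47 per Mb, which was 0.258 of the autosomal density (95% interval 0.237 to 0.280). The median X peak held 12 tags and the median autosomal peak 11. Among autosomes, chromosome 11 was the densest, with 16.8 peaks per Mb and 1.26 times the density of the others (1.21 to 1.32), followed by chromosome 10 at 1.12 times (1.07 to 1.18). Chromosome 18 was the sparsest at 0.821 times (0.770 to 0.874), and chromosome 14 stood at 0.845 times (0.801 to 0.891). Intervals lay above 1 for 5 autosomes, below 1 for 5 and included 1 for 9. Chromosome 7 changed side with the score, from 0.914 times over all peaks to 1.08 times for peaks of a score of at least 100.

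The control list had another distribution. Chromosome X held 31 control regions, 0.659 of the autosomal density (0.444 to 0.943). Chromosome 2 was at 1.58 times the other autosomes (1.23 to 2.01), with the 98.5 Mb locus included, and chromosome 9 also at 1.58 times (1.18 to 2.09). Chromosome 16 was at 0.493 times (0.268 to 0.834). Mitochondrial DNA held 9 control regions with 42 tags and 0 sWGA peaks. Chromosome Y held 11 control regions and 6 sWGA peaks. The Y peak at 2867689 to 2869523 held 214 tags but scored only 77.84. That at 2899057 to 2901079 held 142 tags and scored only 101.45. At the genome-wide rate so many tags would score far higher, so a local background of control tags must have set both scores.

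**Figure D1:**
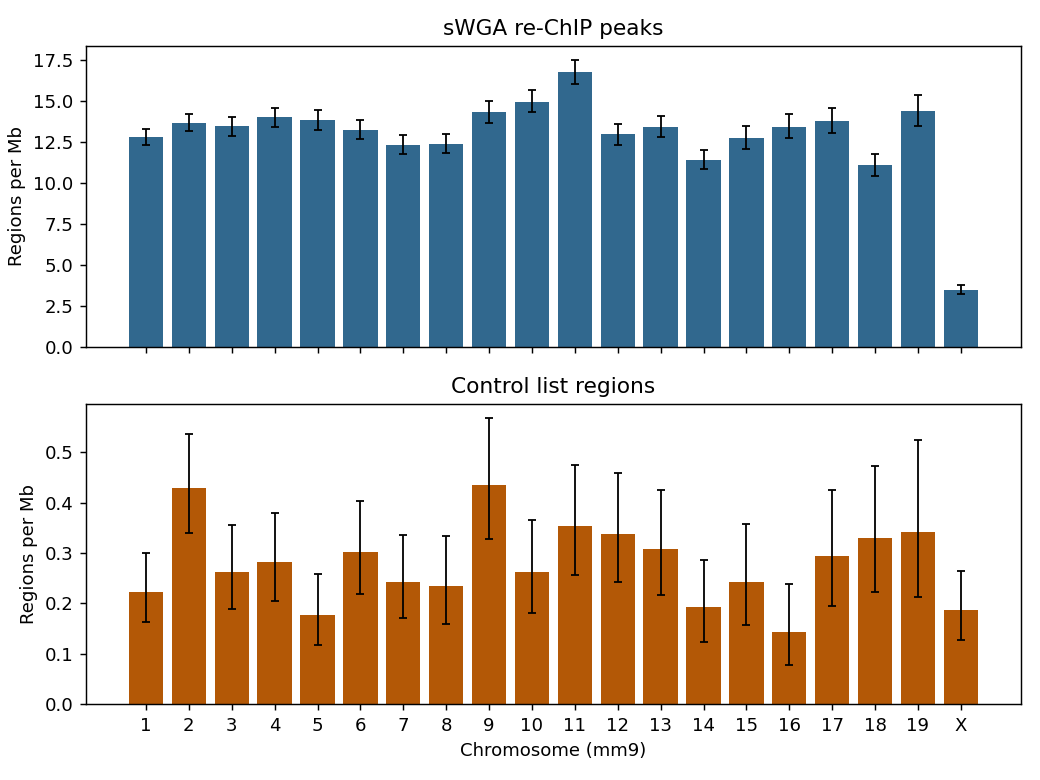
Regions per Mb (vertical axis) on each autosome and chromosome X of mm9 (horizontal axis), for sWGA peaks (top) and control list regions (bottom), with exact 95% Poisson intervals for counting error; chromosome Y and mitochondrial DNA are not drawn. The sWGA density on chromosome X is 3.47 per Mb, below that of every autosome, and chromosome 11 is highest at 16.8 per Mb.

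The sWGA peaks lay close to each other more often than uniformly placed sites would. Of 33783 peaks 8742 (25.9%) had another summit within 5 kb, against a mean of 12.8% and a maximum of 13.7% over 1000 random placements. The share within 1 kb was 7.60% against 2.69%, and within 20 kb it was 53.9% against 42.0%. For peaks of a score of at least 100 the share within 5 kb was 14.4% against 4.55%, a ratio of 3.17 where all peaks gave 2.03. When each summit was moved at random within 250 kb of its own position, which keeps regional density, the mean share was 16.0% and the maximum 16.9%, still below the observed 25.9%. Neither placement takes account of mappability or of 1 enriched stretch called as several peaks, so no cause is read from the excess.

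Joined over gaps of up to 10 kb, the peaks formed 26001 groups, of which 20625 (79.3%) were single peaks and 191 held at least 5. The group with the most peaks lay on chromosome 8 at 19953204 to 20033690, where 29 peaks with 812 tags filled 80.5 kb, and it contains the peak with the highest fold. Chromosome X, though sparse, held the next, with 15 peaks and 442 tags at 121264023 to 121288231. A group of 14 peaks lay on chromosome 1 at 72248393 to 72312401, one of 12 peaks on chromosome 13 at 23583734 to 23628280 and one of 11 peaks on chromosome 19 at 5793026 to 5810622. A second dense group on chromosome X began at 166.4 Mb. The X density was 0.247 of the autosomal one (0.227 to 0.269) without these 2 groups, which hold 25 peaks. Peaks were taken from X alone here, so the ratio could only fall.

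**Figure D2:**
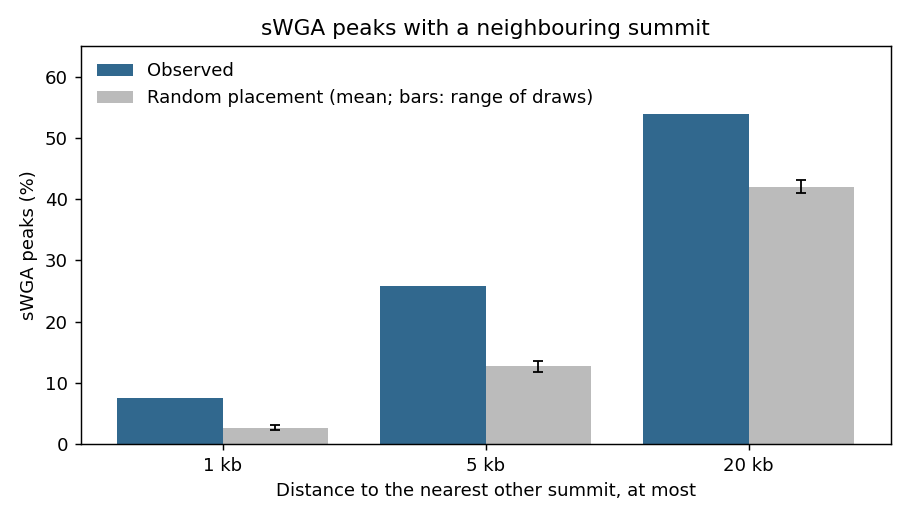
Share of sWGA peaks in percent (vertical axis) with another summit within 1, 5 or 20 kb (horizontal axis), as observed (blue) and as the mean of 1000 random placements (grey, bars from the lowest to the highest draw). The observed share is above every draw at each distance, 25.9% against at most 13.7% at 5 kb.

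The caller's FDR rose with the strength of the peak. The weakest peaks had the lowest FDR, 2.22%, while 746 peaks stood at an FDR of 100%, all at a score of 418.86 or more. Peaks with an FDR of at most 5% numbered 18810, had a median of 10 tags and scored at most 86.16. Peaks at an FDR of 100% had a median of 57 tags and included all 14 peaks named above by fold or score.

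**Figure D3:**
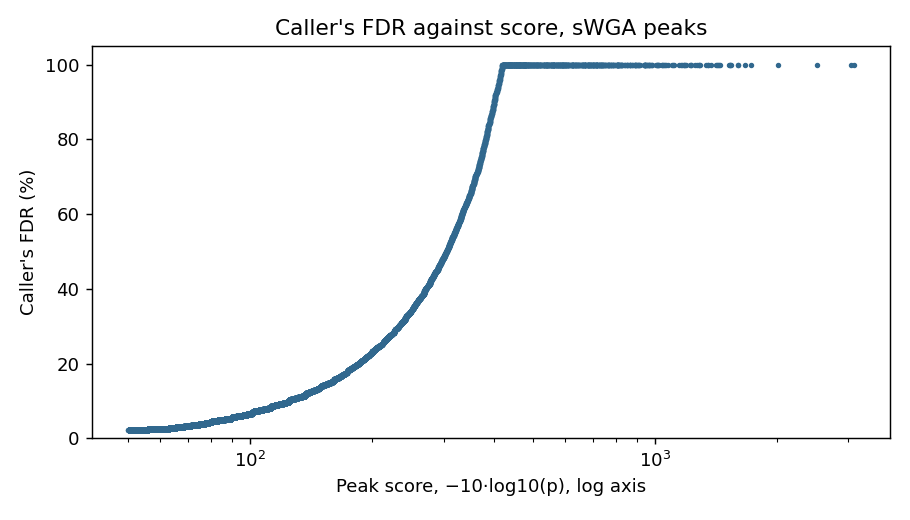
The caller's FDR in percent (vertical axis) against the score, negative log10 of p times 10, on a log axis (horizontal axis), with 1 point per sWGA peak. The FDR climbs from 2.22% at the lowest scores and is 100% for the 746 peaks at the high end.

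Nearly all peaks were scored against a genome-wide background and not against the control near them. The genome-wide expectation was 0.508 tags per fragment length, so that 1 tag at the summit was worth a fold of 1.97. The folds of 30814 peaks (91.2%) were whole multiples of that step within 0.01 tags, a tolerance that would take in 2% of values by chance. Of the other 2969 peaks, 94.4% had folds that were whole tags, at the same tolerance, over the expectation of 1.21 tags that a single control tag within 10 kb sets. Counting all 2969 of these as peaks with a local background, their share was 1.42% at 9 tags (1.12 to 1.77). It was 19.4% at 18 to 29 tags (18.3 to 20.6) and 31.7% at over 60 tags (26.9 to 36.7).

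**Figure D4:**
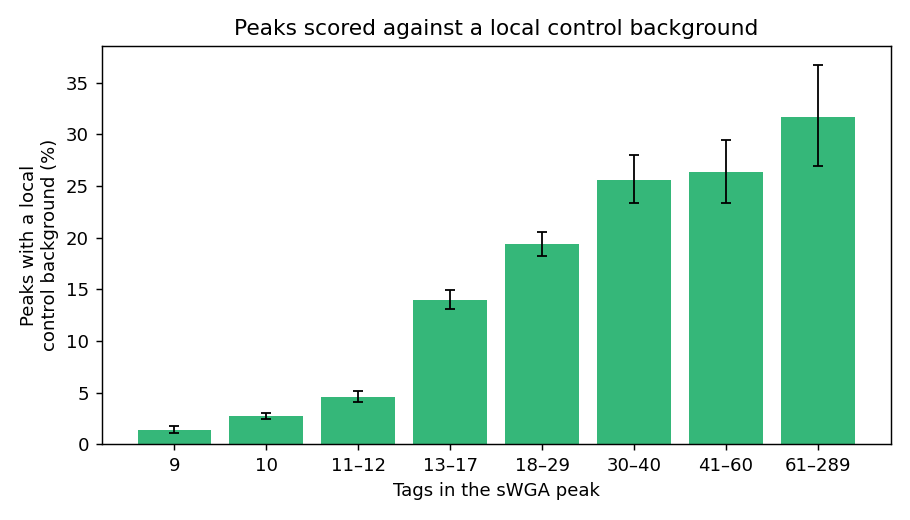
Share of sWGA peaks in percent (vertical axis) whose fold was set by control tags nearby, by the number of tags in the peak (horizontal axis), with exact 95% binomial intervals. The share is 1.42% for peaks of 9 tags and 31.7% for peaks of more than 60.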

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

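No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. With a score of at least 100 the peak count moved from 33783 to 11464, the median length from 419 to 477 bp, the median tags from 11 to 19, the median score from 79.96 to 145.86 and the median fold from 15.75 to 23.62. An FDR of at most 1% left 0 peaks, and an FDR of at most 5%, an alternative added after seeing the data, left 18810. A fold of at least 10 kept 30975 peaks. It kept 1 control region of 750, but control folds are in unscaled tags, so the 2 counts are not comparable. The overlap of 0% between the lists was also 0% against peaks of a score of at least 100, as it must be for a part of the same list. Since the calling kept the lists apart, the placement percentiles of the overlap are not read as a result. The excess of neighbouring peaks kept its direction and its call under the 4 alternatives run. The low density on chromosome X did too, at 0.278 with a score of at least 100. Added after seeing the data, it was 0.309 with at least 18 tags and 0.277 with peaks within 10 kb counted as 1. Leaving out 2 dense groups took peaks from X alone. That could only lower the ratio, to 0.247, and is no check. The ratio of chromosome 7 reversed, to 1.08 with a score of at least 100 and to 1.13 with at least 18 tags, and the cause was not tested. Of 57 alternative values for single autosomes, 38 kept their call (an interval above, below or including 1), 11 came to include 1, 6 no longer did and 2 reversed (chromosome 7). Of the 10 autosomes whose interval excluded 1, chromosomes 11, 14 and 18 kept that call under all 3 alternatives. The control library was shallow, and 3 tags made a region there.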

Other observations

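Of the tests below, those on threshold selection over all tag numbers and at 9 to 10 tags, the estimate with shortened regions and the check without 2 dense X groups were chosen after the result was seen. The others were set before their result was seen, on patterns found in the same data.

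The low peak density on chromosome X may follow in part from a single X copy in these cells, a hypothesis that the labels do not address. Chromosome Y held 11 control regions and 6 sWGA peaks, as cells with 1 X and 1 Y would give. The number of X copies was not measured. With tags thinned at a probability of 0.5 and scored again, 27.2% of autosomal peaks passed the caller's limit at full region length, 29.3% with regions shortened as tags were lost, and 56.3% at 50% of the length, where the observed X share was 25.8% (23.7 to 28.0). At a score of at least 100 thinning kept 21.3% at full length, below the observed 27.8% (24.2 to 31.9). With shortened regions it kept 22.3%, against 27.0% (23.4 to 30.9) for X peaks scored again without the 2 dense groups. Equal thinning at these lengths thus gave fewer strong X peaks than observed. Regions at 50% of the length were not run at this score, so a single X copy is not excluded for strong peaks. A denser control background on X stays open. It was found at 32.0% of X peaks of at least 18 tags (24.5 to 40.2) against 21.8% on autosomes. Without the 2 dense X groups the X share was 28.5% (20.9 to 37.0). The autosomes kept their own dense groups, so 21.8% is no like reference for that share. X held 0.659 of the autosomal density of control regions (0.444 to 0.943), and peaks lost beside a control tag are not in these shares. Neither mappability nor a biological explanation was tested.

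The rise of the local control background with peak strength is consistent with selection at the calling limit among weak peaks. Scored again with 1 control tag in 10 kb, 94.0% of the peaks of 9 to 10 tags that had the genome-wide background fell below the limit. Peaks this weak lie near the limit, so the loss of most of them was given by the caller's arithmetic. A single control tag may thus decide whether such a site is listed, but how many sites were lost in this way was not measured. Among stronger peaks the share rose further, from 25.6% at 30 to 40 tags to 31.7% over 60 tags, a difference of 6.07 percentage points (Newcombe 95% interval 0.923 to 11.5), but a control tag within 1 kb would remove every peak of 30 to 40 tags and leave 19.8% of those over 60, so selection stays open there too. Counting only peaks with exactly 1 control tag in 10 kb or none, all of which pass at these tag numbers, the difference was 1.83 points (-2.90 to 7.11), but this leaves out sites with nearer or more control tags. Whether control tags gather at the strongest sites, as carry-over of Flag-Oct4 chromatin would give, therefore stays open, and the 34.2% of the genome that evenly spread control tags would put within 5 kb of one is no fair reference for the 31.7%, since peaks beside control tags were lost. With 1 control library no biological explanation was tested.

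The rise of the FDR with peak score follows from how the FDR was computed. The high control scores behind it may come from scaling the small control library up to the large one. The deposited FDR was recomputed within 0.01 percentage points for 99.4% of peaks as the number of control regions over the number of peaks at the same score or higher. Of 750 control regions 685 scored 3100 or more, a score that 1 peak reached, so the ratio rises as fewer peaks remain. With control regions scored at the control library's own rate, 34 of them passed the score of the top 10% of peaks. That gives 1.01% in place of 22.2%, and the value for the whole list stayed at 2.22%. The 1.01% is no corrected error rate. At the control's own depth the median control region scored 97.8, against 195.99 at the top 10%, so few could pass. All 750 still passed the limit of 50, which fixed the 2.22%. The deposited FDR, used as a limit on this list, would keep the weak peaks and drop the strong ones, while a limit on score or tags would not. No biological explanation was tested.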
